A study of Mus musculus with 15 samples.

How the data were processed

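The series profiled the nucleus accumbens, a ventral striatal region of the reward circuit, of C57BL/6 mice given 7 daily intraperitoneal injections of cocaine at 20 mg/kg or saline. It holds 15 libraries. DNA carrying 5-hydroxymethylcytosine (5hmC), the oxidation product that Tet enzymes make from 5-methylcytosine, was captured and sequenced in 3 cocaine and 3 saline libraries. Histone H3 acetylated at lysine 27 (H3K27ac), a mark of active enhancers and promoters, was profiled by ChIP-seq in 3 cocaine and 3 saline libraries, with 1 input library for each treatment. The remaining library is named as cerebellum input in one label field and as nucleus accumbens in the tissue field, so it entered no comparison. The labels do not say whether the 3 libraries of a group came from separate animals. The p-values from limma and from exact permutation of libraries therefore measure the spread between these libraries, which may be technical. For most H3K27ac regions limma took that spread from a trend over regions, not from the region itself. The Fisher tests, circular shifts and permutations of direction were computed over regions and contain no spread between libraries.

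Reads were aligned to mm9 with Bowtie 0.12.9, per the submitters' processing notes. The H3K27ac table was made with diffReps 1.54, per the file headers, using a negative binomial test on windows of 1000 bp moved by 100 bp, with a window p of at most 0.0001. The 5hmC table has no header lines; its columns have the same names, its windows are 200 bp wide, and its caller is not given in the sources used here. Both tables were deposited as lists of regions that had passed the caller, not as a scan of the genome. The deposited signal of each group is the mean of 3 normalised read counts per region, and the per-library values stand beside it. The deposited ratio columns divide each group mean by a background library. The log2 fold change of cocaine over saline was computed by the authors from the means of the normalised counts. The p-value and adjusted p-value of each region are those of the authors' caller. The authors' deposited lists of cocaine-specific and saline-specific 5hmC enhancers hold intervals on a grid of 200 bp; how they were made is not given in the sources used here, and their positions were taken as mm9.

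The normalised counts were whole multiples of 1 step per library, within a tolerance of 0.1 read in 100.0% of the values checked. In the 5hmC table the step was 0.899 to 1.24 for cocaine libraries and 0.897 to 1.03 for saline libraries, and the median depth was 5.00 to 7.00 reads per region in each library. In the H3K27ac table the median was 473 to 534 reads per region. Replicate numbers in the H3K27ac comparison follow the library names in the file headers, and those in the 5hmC comparison are only the position in the table. No per-library column was left unused (0 columns).

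Because the values are normalised counts rather than raw counts, the count test planned before the data were examined was replaced by limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean-variance trend, robust variance moderation and Benjamini-Hochberg adjustment. Fold changes from limma are on that scale and understate the change of low regions. Plain variance moderation was run first. For H3K27ac its prior degrees of freedom were infinite in all regions, so no region kept its own variance and the most variable regions received standard errors far below their own spread. Robust moderation was adopted for that reason after the results of the plain fit had been seen, and it gave 850 H3K27ac regions a finite prior. The remaining regions still take their variance from the trend. Tested on simulated data with 3 against 3 libraries and 49712 H3K27ac regions, the procedure recovered 89% of 100 regions changed 1.25-fold and 100% of 100 regions changed 1.5-fold, with 8 calls among unchanged regions. With 11748 5hmC regions it recovered 3% of 100 regions changed 2-fold and 55% of 100 regions changed 4-fold, with 1 call among unchanged regions. The simulated libraries were independent. All regions of a mark had 1 common coefficient of variation beyond counting noise, 0.0171 for H3K27ac and 0.1031 for 5hmC. No factor shared by regions within a library and no unusually variable regions were simulated. The calls among unchanged regions therefore do not measure the error rate in the real data.

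Overlap meant at least 1 shared bp and was compared with 1000 circular shifts within each chromosome by a one-sided permutation test. Directions were compared with Fisher's exact test, two-sided. Chromosomes with at least 20 regions were each compared with the rest, with Benjamini-Hochberg adjustment. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives planned before the data were examined were other thresholds, a minimum fold change or depth, leaving out each library, leaving out the sex chromosomes, and other definitions of overlap. Other pseudocounts, median centring, cyclic loess, plain moderation, unmoderated variances and sums per library were added after the data had been seen.

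No mm9 annotation was used here, so regions were assigned to no gene or feature, and the planned comparisons of genomic features, gene lists and genes with both marks were not run. The planned rule for named genes therefore became a rule for regions. For each table and direction the 8 regions with the smallest deposited adjusted p were taken, ties going to the larger absolute log2 fold change, with up to 10 overlapping pairs of both marks by the larger absolute 5hmC log2 fold change. Some of these are printed below as examples. The 5 regions with the largest fold change per direction and the 100 regions with the largest H3K27ac decreases were singled out after their values had been seen.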

Results

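Levels of 5hmC and H3K27ac in the nucleus accumbens were compared between mice given 7 daily cocaine injections and mice given saline, with 3 libraries per treatment for each mark. The series title places the comparison in the study of Tet1 and 5hmC in cocaine action. The 5hmC table listed 11748 regions with a median length of 200 bp, and the H3K27ac table listed 49712 regions with a median length of 1200 bp. All positions are in mm9. Pearson's r across regions was 0.776 to 0.811 within groups and -0.277 to -0.217 between groups for 5hmC, whose regions had been selected for a group difference. For H3K27ac it was 0.994 to 0.996 within and 0.986 to 0.993 between groups. Regions are not independent replicates.

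The first comparison asked where 5hmC differed after cocaine. Of the 11748 regions in the authors' deposited table, 6874 (58.5%) were higher and 4874 (41.5%) were lower after cocaine. The changes were large on low counts. Regions higher after cocaine had a median log2 fold change of 2.01, with median group means of 9.0 normalised counts in cocaine and 2.25 in saline. Regions lower after cocaine had a median log2 fold change of -2.08, with 2.15 normalised counts in cocaine and 8.98 in saline.

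In the authors' deposited table the largest adjusted p of the 11748 regions was 0.1495, and the largest window p was 0.0009998. The list thus reached well above an adjusted p of 0.05, and 4 of its regions lay below that value. On chromosome 17, the region from 31975601 to 31976040 held 29.4 ± 3.68 normalised counts in cocaine and 9.04 ± 2.46 in saline (SD, n = 3 each). The region on chromosome 11 from 89266621 to 89267000 held 16.9 ± 0.641 in cocaine and 3.57 ± 1.59 in saline. The other 2 were lower after cocaine and both lay on chromosome 5. The region from 20435401 to 20435840 held 3.85 ± 1.77 normalised counts in cocaine and 18.8 ± 2.79 in saline, and the region from 147090821 to 147091160 held 2.27 ± 0.905 and 14.4 ± 2.28. Their log2 fold changes in the authors' deposited table were 1.70, 2.25, -2.29 and -2.67, with adjusted p of 0.0163, 0.0253, 0.0163 and 0.0474. In all 4 regions the 3 cocaine values did not overlap the 3 saline values. The same held for 11739 of the 11748 listed regions (99.9%), which had been selected for a group difference.

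**Figure D1:**
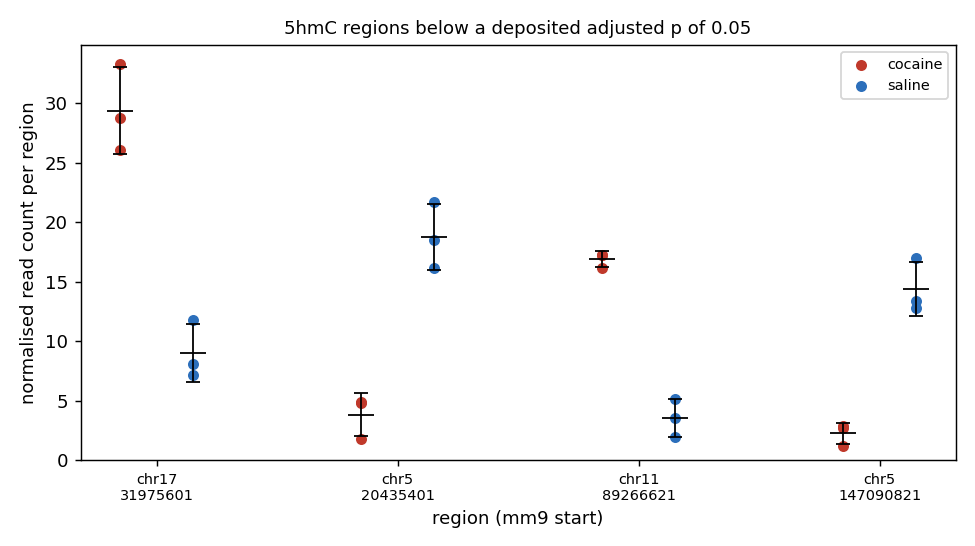
Normalised read counts (y axis) of the 4 5hmC regions below a deposited adjusted p of 0.05 (x axis, mm9 start), with each library as a point and the mean ± SD of 3 libraries as black bars. Cocaine libraries lie above saline libraries on chromosomes 17 and 11 and below them in both regions on chromosome 5.

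Among regions above that threshold, chromosome 7 from 25348521 to 25348780 held 11.7 ± 2.44 normalised counts in cocaine and 1.55 ± 1.39 in saline (SD, n = 3 each). Chromosome 5 from 111865741 to 111866140 held 3.54 ± 3.25 and 17.0 ± 2.31. Their deposited adjusted p values in the authors' deposited table were 0.0770 and 0.0578. On chromosome 4 from 124398841 to 124399140 all saline libraries were listed at 0 and cocaine held 6.49 ± 0.842, at least 6.68-fold higher than a floor of 3 reads over the saline group. A test of the listed regions on the same 6 libraries is circular, since the regions had been selected for their difference in those libraries: limma called all 11748 of 11748. The median was 5.00 to 7.00 reads per region and library. In simulated data of 11748 regions limma recovered 3% of 100 regions changed 2-fold and 55% of 100 changed 4-fold. The other simulated regions were unchanged, whereas all listed regions had been selected for a difference. The simulated shares therefore do not give the recovery in this list.

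The second comparison asked where H3K27ac differed. Changes were small: regions higher after cocaine had a median log2 fold change of 0.05, and regions lower after cocaine one of -0.06. The authors' deposited table held 23566 regions (47.4%) that were higher and 26146 (52.6%) that were lower. With limma, 6479 of 49712 regions passed an adjusted p of 0.05, of which 1699 were higher and 4780 were lower after cocaine. Libraries of the same group stood apart in the lower regions. Saline library 3 exceeded saline library 2 in 88.1% of them, and cocaine library 3 exceeded the mean of the other cocaine libraries in 86.55%. Over all regions these shares were 63.2% and 49.4%. The median differences between these libraries were 0.801 and 0.427 times the median group difference in the lower regions. In the higher regions they were 0.0836 and 0.13 times it. After cyclic loess scaling, chosen after the data had been seen, the counts were 2735 higher and 4714 lower. The 3 cocaine values did not overlap the 3 saline values in 29.1% of regions; unselected regions give 10% by chance, but these had been selected in the same libraries.

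On chromosome 5, the region from 117802201 to 117803200 held 187 ± 5.24 normalised counts in cocaine and 145 ± 7.20 in saline (SD, n = 3 each), with a limma log2 fold change of 0.37 ± 0.0699 (SE, adjusted p = 1.07e-05). On chromosome 7, the region from 53690901 to 53691900 held 214 ± 7.94 and 167 ± 14.4, with a limma log2 fold change of 0.36 ± 0.0659 (adjusted p = 3.61e-06). Among regions lower after cocaine, chromosome 2 from 143836401 to 143837800 held 265 ± 15.1 in cocaine and 358 ± 16.9 in saline, with a limma log2 fold change of -0.44 ± 0.0541 (adjusted p = 6.90e-13). Chromosome 4 from 151525501 to 151526500 held 175 ± 13.0 and 239 ± 18.7, with a limma log2 fold change of -0.45 ± 0.0637 (adjusted p = 7.27e-10). The largest decrease, on chromosome 10 from 7675401 to 7676600, had 216 ± 53.8 normalised counts in cocaine and 420.5 ± 134 in saline and did not pass (limma log2 fold change -0.94 ± 0.333, adjusted p = 0.178).

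The H3K27ac regions, like those of 5hmC, each held a window that had passed the caller for cocaine against saline in these same 6 libraries, so the limma calls are not an independent test of a difference. They also rest on variances shared between regions: with each region's own variance, 2 of 49712 regions passed and 8528 had an unadjusted p below 0.05, and without cocaine library 1, cocaine library 2 or saline library 3 limma called 3082, 3055 or 3696 regions.

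The direction of the H3K27ac change followed the signal level. In the lowest decile of level, 62.9% of 4972 regions were higher after cocaine, and limma called 901 higher and 610 lower. In the highest decile, 21.8% of 4972 regions were higher, and limma called 0 higher and 940 lower. After cyclic loess the called regions in the highest decile were 156 higher and 608 lower. Those in the lowest were 454 higher and 1094 lower, so lower calls outnumbered higher ones there. The median log2 fold change of all regions in the lowest decile stayed positive (0.10 before and 0.06 after loess). In the highest decile that median went from -0.044 to -0.010, so part of the trend with level depended on the scaling.

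**Figure D2:**
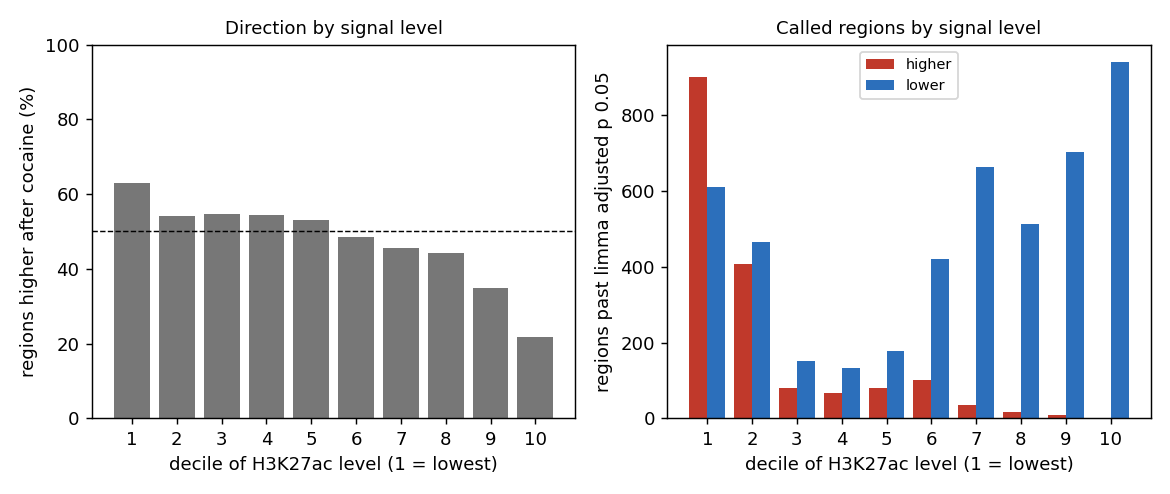
Left, percentage of H3K27ac regions higher after cocaine (y axis) by decile of H3K27ac level (x axis), with a dashed line at 50%. Right, number of regions past a limma adjusted p of 0.05 (y axis) by the same deciles, higher in red and lower in blue; the share falls from 62.9% in the lowest decile to 21.8% in the highest.

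By chromosome, 28.8% of 413 H3K27ac regions on chromosome X were higher after cocaine (95% exact binomial interval 24.5% to 33.4%), against 47.6% elsewhere (odds ratio 0.446, Fisher's exact test, adjusted p = 2.54e-13). Chromosomes 4 and 11 also had fewer higher regions than the rest, 43.3% and 45.0%, and chromosome 12 had more, 52.4% (adjusted p = 1.12e-05, 0.00686 and 1.65e-06). For 5hmC no chromosome passed: 36 of 50 regions on chromosome X were higher, with an adjusted p of 0.732 and an unadjusted p of 0.0610 by Fisher's exact test. Of the 20 H3K27ac tests, 4 passed. Among limma-called regions chromosome 4 did not pass (adjusted p = 0.253) and chromosome 13 did, with 34.7% higher (adjusted p = 0.00812). These tests treat regions as independent; by library, chromosome X held 0.695% ± 0.00649 of the normalised H3K27ac counts in cocaine and 0.712% ± 0.00617 in saline (SD, n = 3 each, exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 libraries allow).

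Overlap of the marks was examined next. Of the 11748 5hmC regions, 1052 (8.96%) overlapped an H3K27ac region, 2.72 times the mean of 387 over 1000 circular shifts (permutation p = 0.001, the smallest they can give). The shifts moved regions over the whole span of each chromosome, and no unchanged regions of either mark were available for comparison. The excess therefore cannot tell coinciding changes from coinciding marks. Regions higher and lower in 5hmC overlapped H3K27ac regions at 9.02% and 8.86% (Fisher's exact test, p = 0.793). No association of the directions was detected. Limma called 107 of the 1127 H3K27ac regions with a 5hmC region (9.49%). Most H3K27ac directions in the pairs are therefore signs of changes that did not pass, which limits what this comparison can detect. Among 1137 overlapping pairs, higher 5hmC went with higher H3K27ac in 338 and lower in 334, and lower 5hmC went with higher H3K27ac in 240 and lower in 225 (odds ratio 0.949, Fisher's exact test, p = 0.673).

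Of the 10 overlapping pairs with the largest 5hmC changes, 5 had the same direction in both tables and 5 had opposite directions. Only the H3K27ac region from 77809701 on chromosome 12 passed limma's adjusted p of 0.05. The H3K27ac regions of the other pairs had limma adjusted p of 0.104 to 0.728, so their directions are not established. In an opposite pair on chromosome 12, the 5hmC region from 77811861 to 77812060 had 5.46 normalised counts in cocaine and 0.33 in saline in the authors' deposited table, and the H3K27ac region from 77809701 to 77812600 had a limma log2 fold change of -0.17 ± 0.0357 (SE, adjusted p = 8.93e-05). In a pair with the same direction, on chromosome 4 from 118906981 to 118907180, 5hmC had 6.31 normalised counts in cocaine and 0.60 in saline in the authors' deposited table. H3K27ac over 118906601 to 118907600 had a limma log2 fold change of 0.12 ± 0.0578 (adjusted p = 0.172).

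The deposited enhancer lists held 10575 cocaine-specific and 10555 saline-specific intervals. Regions higher in 5hmC after cocaine overlapped the cocaine-specific list more often than regions lower after cocaine, 160 of 6874 (2.33%) against 22 of 4874 (0.451%), with an odds ratio of 5.26 (Fisher's exact test, p = 2.92e-18). The saline-specific list showed the opposite, 37 (0.538%) against 95 (1.95%), with an odds ratio of 0.272 (Fisher's exact test, p = 1.57e-12). The lists carry the name of the same mark and may come from the same libraries, so this is not independent evidence. Higher and lower regions reached 9.59 and 1.86 times the mean of the shifts at the cocaine-specific list (permutation p = 0.001, the smallest they can give, and 0.012), and 2.27 and 8.07 times at the saline-specific list (permutation p = 0.001 for each). With at least 50% of a region covered, lower regions at the cocaine-specific list no longer passed (1.61 times, permutation p = 0.08). Only 1.72% and 1.24% of the intervals of these lists overlapped a 5hmC region.

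H3K27ac regions overlapped both lists less often than circular shifts. The numbers of higher and lower regions were 0.558 and 0.487 times the mean of the shifts at the cocaine-specific list, and 0.281 and 0.330 times at the saline-specific list; the permutation test, one-sided for more overlap, gave p = 1.0 for each. H3K27ac direction did not differ detectably at either list. At the cocaine-specific list 101 higher and 103 lower regions overlapped (odds ratio 1.09, Fisher's exact test, p = 0.574), and at the saline-specific list 51 and 70 (odds ratio 0.808, p = 0.274). Regions overlapping the cocaine-specific list held 0.475% ± 0.00157 of the normalised H3K27ac counts in cocaine and 0.471% ± 0.00103 in saline (SD, n = 3 each, exact permutation test, two-sided, p = 0.1, the smallest that 3 against 3 libraries allow). For the saline-specific list the shares were 0.234% ± 0.000807 and 0.234% ± 0.000218 (exact permutation test, p = 0.400).

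**Figure D3:**
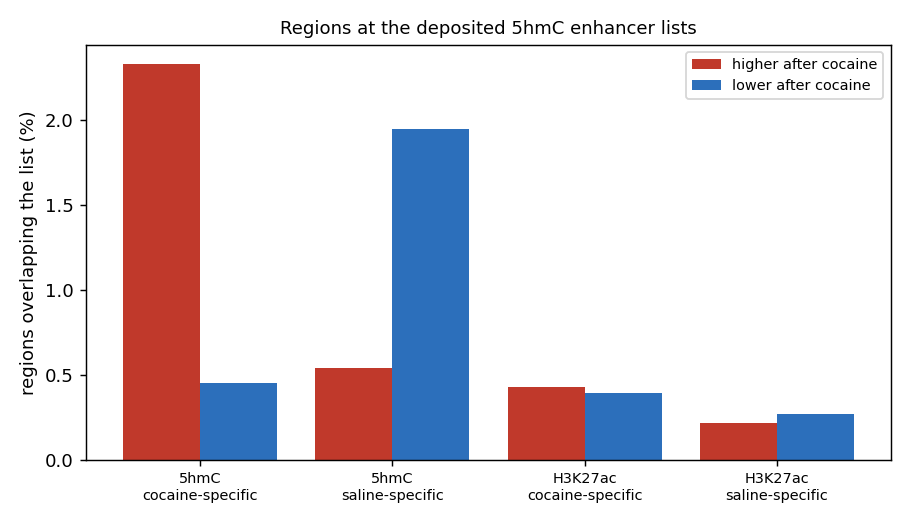
Percentage of 5hmC and H3K27ac regions (y axis) that overlapped each deposited enhancer list (x axis), for regions higher (red) and lower (blue) after cocaine. For 5hmC the taller bars are 2.33% of higher regions at the cocaine-specific list and 1.95% of lower regions at the saline-specific list.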

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

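In 226 of the 11748 5hmC regions (1.92%), the background behind the deposited ratios exceeded the mean of both nucleus accumbens groups. It came up because those ratios enter no comparison. Ranked by the larger ratio of each region, the most extreme of these, on chromosome 11 from 3074281 to 3074640, had deposited ratios of 0.14 in cocaine and 0.06 in saline. The background was 0 in 1766 regions (15.03%). The 5hmC table has no header lines to say which library served as background, and no explanation was tested.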

How the results depend on the processing

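The added alternatives, chosen after the data had been seen, were the pseudocounts, scalings, variance moderation and sums per library. For H3K27ac, limma called 6479 regions, and from 3055 to 6918 when 1 library was left out, with the lowest counts without cocaine library 2 (3055), cocaine library 1 (3082) and saline library 3 (3696). It called 3259 at an adjusted p below 0.01, 0 at an absolute log2 fold change of at least 1, and 2 with each region's own variance; the cause was not tested. Plain moderation gave 6412 regions and also called the 5 regions with the largest decreases, which were chosen after their values had been seen and which robust moderation did not call. Robust moderation called 4 of these 5 without saline library 2 and 3 of them without saline library 3. The share of higher regions among those called was 26.2%, against 15.3% at an adjusted p below 0.01 and 36.7% after cyclic loess. Of the 17 H3K27ac regions taken by the naming rule that passed, 17 no longer passed with their own variance, and 0 were lost in any fit that left out 1 library. The named region on chromosome 14 at 22642301, not called, ranged from -0.0397 to 0.0104 on the log2 scale when 1 library was left out, the latter without cocaine library 1.

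For 5hmC, the deposited table held 4 regions below an adjusted p of 0.05, 0 below 0.01 and 7 below 0.1. Its largest adjusted p was 0.1495. The circular limma count was 11748, between 11743 and 11748 with 1 library left out, and 4775 where 1 group mean was at least 10, since only 4775 regions were tested. For H3K27ac the deposited table held 32739 regions below 0.05, and 0 of these had an absolute log2 fold change of at least 1. The ratio of overlap to shifts was 2.72, and 0 at a deposited adjusted p below 0.05, where 4 5hmC regions were left. The odds ratio for direction agreement, 0.949, reversed to 1.01 with at least 50% of a region covered and 1.05 within 1000 bp, and that of H3K27ac at the cocaine-specific list, 1.09, reversed to 0.915 within 1000 bp; none passed its test, and the cause was not tested. Overlaps at a 5hmC adjusted p below 0.01 had no regions, and the 4 regions below 0.05 overlapped neither enhancer list. Lower 5hmC regions at the cocaine-specific list went from 1.86 times the shifts (permutation p = 0.012) to 1.61 times (permutation p = 0.08) with at least 50% covered, on 12 regions instead of 22. Count tests with other size factors, genomic features, gene lists and genes with both marks were not run. Low 5hmC depth limits that table, shared variances limit H3K27ac, and selection of regions in the same libraries limits both.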

Other observations

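The tests of the counting interval, of region length, of the saline libraries, of a shared factor, of neighbouring 5hmC regions, of distances between the lists and of limma calls at 5hmC regions were not planned and were chosen after the data had been seen. The tests of libraries repeating small differences, of signal level, of chromosome X and of splits were set before their results were seen. Cocaine-specific and saline-specific enhancer intervals never overlapped, yet 387 of 10575 cocaine-specific intervals (3.66%) lay within 1000 bp of a saline-specific one, against a mean of 122 over 1000 circular shifts (permutation p = 0.001, the smallest they can give). Fewer H3K27ac regions with a 5hmC region were called by limma, 107 of 1127 (9.49%), than others, 6372 of 48585 (13.1%, Fisher's exact test, p = 0.000238). The comparison was not matched on signal level or length. Limma called 9.28% of regions of 1000 bp and 17.6% of those over 1500 bp.

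Of 620 neighbouring pairs of 5hmC regions within 5000 bp, 55.3% changed in the same direction, against a mean of 51.4% over 10000 permutations of direction within chromosomes (one-sided permutation p = 0.0279). This is in line with shared changes over neighbouring regions, a hypothesis tested on the data it came from.

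Deposited adjusted p values below 0.05 covered 32739 H3K27ac regions, with a median absolute log2 fold change of 0.06. Libraries did not overlap in 30.7% of regions below that threshold and 26.1% of those above it, 4.60 percentage points apart. In the other regions below it the values overlapped. There this argues against small differences that every library repeats as the reason for the small p. For the 30.7% that explanation stays open. Regions on both sides had passed the caller in these same libraries, so the contrast between them cannot decide. The cocaine to saline ratio lay inside its 95% counting interval in 76.3% of the regions below 0.05 and 78.2% of those above it. Such similar shares would arise if the deposited p did not measure the difference between the group means. The share below 0.05 was 100% at 1000 bp and 52.8 percentage points lower in longer regions. A region of 1000 bp has the length of the caller's window. To be listed, a region had to hold a window with p of at most 0.0001. The 100% therefore followed from the listing rule. Its contrast with longer regions cannot decide whether merging of windows sets which regions keep a small p. Among longer regions the share was 36.9% at 1100 to 1500 bp but 58.0% above 1500 bp, which a simple account by merging leaves open. No biological explanation was tested.

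The 100 H3K27ac regions with the largest decreases lay on 20 chromosomes, and 63 passed limma's adjusted p of 0.05. Saline library 3 exceeded saline library 2 in 98% of them, and cocaine library 3 exceeded the mean of the other cocaine libraries in 100%. Over all regions these shares were 63.2% and 49.4%. Independent noise of single libraries is argued against as the whole cause: in 100 regions picked on library 1 of each group alone, 81 of them among the former, saline library 3 minus saline library 2 was 0.391 above that of all regions (95% bootstrap interval 0.346 to 0.445). After cyclic loess 1.05 times the median log2 fold change remained. This could not decide on a trend with signal level, since loess moved the median of the lowest decile only from 0.099 to 0.064. The median level of the 100 regions, 253 normalised counts per 1000 bp, lay in that decile. The median change there was upward, which argues against that trend as the cause of decreases at this level. One factor that differs between animals as well as between groups, such as another cell type in the dissection, may contribute but stays open: differences within groups were 0.903 times the group difference in saline and 0.398 times in cocaine, and an effect of cocaine itself also stays open.

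The lower H3K27ac on chromosome X was not matched by autosomal regions of the same signal level, of which 49.0% were higher after cocaine, 20.2 percentage points above chromosome X. The medians of chromosome X and autosomes differed by 0.031 on the log2 scale. A different number of X chromosomes between the groups stays open, since H3K27ac need not scale with that number. No library alone carried it: with 1 library left out the gap to autosomes stayed at 15.9 percentage points or more. A response of the X chromosome to cocaine may be one hypothesis, and other differences between the libraries stay open; at the level of libraries the exact permutation p was 0.1, the smallest possible.

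Of the 10 splits of the 6 H3K27ac libraries, 1, the real one, gave as many as 6479 regions, and the highest other gave 1129. For 5hmC the real split gave 11748 regions and the highest other 0. The regions of both tables had been selected by the real split, which favours it. With 10 splits no share below 0.05 can be reached.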
